A study of Mus musculus with 8 samples.

How the data were processed

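Gene expression was measured in hearts of male C57BL/6N mice aged 19 weeks that lacked Mfap4, which encodes microfibril-associated protein 4, an extracellular matrix glycoprotein. RNA from each of 4 knockout mice was hybridised to 2 spotted cDNA arrays against a pool of wild-type heart RNA, with the dyes exchanged between the arrays, which gives 8 arrays. The labels differ on the pool: the labelling protocol states 6 control animals, while the channel labels list 4 mice and the design text names 4. No control mouse was hybridised singly.

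The spot values are median pixel intensities of the spot and of its local background in each channel, on a linear scale with no normalization, per the file headers. The image software is not given in the sources used here. Per the labels, total RNA was reverse transcribed and labelled indirectly with Cy3 or Cy5. The column of spot flags in the deposited files is 0 on every spot of the arrays of mice 1 and 2, and marks between 28.2% and 43.0% of spots on the arrays of mice 3 and 4. The authors' processed value table holds a score per spot whose scale, centring and direction are not given in the sources used here. Set against the scanner values, each of its columns followed the log2 ratio of mouse over pool after background subtraction (Spearman's rho across spots at least 0.998), with 1 constant added per array. Over 99.5% of its values lay within 0.01 of that ratio plus the constant. What sets the constant remains unknown. The column medians for mice 1 to 4 were -0.14, 0.024, -0.032 and -0.094 with the mouse in Cy3, and -0.17, -0.13, -0.31 and -0.58 with the mouse in Cy5. Values beyond 20 in size, at most 19 per array, were left out.

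Intensities were corrected with normexp (offset 50) and normalized by loess within each array in limma 3.58.1 under R 4.3.3, with weight 0 for spots carrying a flag, which were then left out. Each log2 ratio was turned to knockout over pool from the dye labels. Spots of 1 clone were averaged, and the 2 dye-swapped arrays of a mouse were averaged into 1 value, so that n = 4 mice. The 8142 of 20160 clones with a value on all 8 arrays were tested with an intercept-only limma fit against 0 and Benjamini-Hochberg adjustment, with a threshold of 0.05. This test leaves out the spread between control mice, and a departure of the pool from the average control enters all 4 ratios alike. The number of arrays limits the precision. No scan date or slide was used as a batch, since none is recorded in the file headers; mice 1 and 2 against mice 3 and 4, which differ in spot flags, were tried as a term in the fit.

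Clones carry old accessions, named here only through the RefSeq gene table of assembly GRCm38.p6. Of 20205 spots, 964 matched a RefSeq transcript and 500 a synonym or symbol, giving 1387 genes. Of the remainder, 6312 carry no accession and 12429 an accession that did not match. No coordinates are printed, since the files name no build; the table served for names and for which genes neighbour Mfap4.

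The tests, the alternatives, 35 gene lists and the rule for naming genes were fixed before the data were examined. In the lists and near Mfap4 a gene was represented by its brightest clone; the rule for naming genes worked on single clones. Lists with at least 5 tested genes were tested with camera, with a preset correlation of 0.01 between genes and unnamed clones in the background. Genes were to be named if they passed the threshold with 1 sign on all 8 arrays. Failing that, those with the smallest unadjusted p and 1 sign on all 8 arrays were taken, up to 10 per direction. The members with the smallest p of any list past the threshold were to be added, and 12 genes of matrix, integrins and heart stress whatever their values. Genes named beside their lists or their neighbours of Mfap4, and Timm10 and Gfra1, were chosen after their values were seen.

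The fit was tested on simulated scanner values built on the 8142 clones, with the real brightness, background, flags and dye effects and with 50 clones changed at each of 4 sizes. Of clones changed by a log2 ratio of 1, 94% were recovered, and of those changed by -1, 96%. At 0.5 and -0.5 the shares were 52% and 40%. There were 6 false calls. The median log2 ratio found for a true 1 was 0.70, so the ratios are compressed. The simulated dye effects and noise were taken from ratios already compressed in this way, and were compressed again. Noise was drawn for each array separately, with no part shared by the 2 arrays of a mouse. The shares recovered can therefore be too high for the real arrays. The alternatives covered background correction, normalization, spot flags, dim clones, dye orientation, the use of the 8 arrays, the authors' value table, each mouse left out and the variance prior. Random blocks used statmod 1.5.0, and set tests for random blocks and for the trended prior used cameraPR on the moderated statistics of those fits. Figures were drawn with matplotlib 3.10.9.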

Results

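The arrays compared the heart RNA of 4 Mfap4 knockout mice with a pool of wild-type heart RNA, in a study of MFAP4 as an integrin ligand in vascular remodelling. Each mouse was hybridised on 2 arrays with exchanged dyes. Most spots were dim. Between 8.03% and 23.8% of spots per array exceeded 2 times the local background in Cy5, and between 4.65% and 35.9% in Cy3. Only 609 of the 8142 tested clones had a gene name, for 586 genes.

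Mfap4 itself was not measured under a name, so the knockout could not be checked on the arrays. The same holds for the integrin subunits Itgav, Itgb3 and Itgb5, for fibrillin-1 (Fbn1), for the collagens Col1a1 and Col3a1, for smooth muscle actin (Acta2), and for Nppa, Nppb and Myh7, which mark cardiac stress. Eln, which encodes elastin, and Lox, the enzyme that cross-links elastin and collagen, were on the array, but spot flags kept them out of the test. With all spots kept, the log2 ratio of Eln was -0.0050 ± 0.084 (SE, n = 4 mice). The 2 Lox clones had log2 ratios of 0.30 ± 0.20 and 0.063 ± 0.094 (SE, n = 4 mice). The higher value rested on mouse 2, at 1.25, while the other mice lay between -0.039 and 0.015.

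Gene activity in the knockout hearts was compared with the wild-type pool across all tested clones. Among named genes with 1 sign on all 8 arrays, the clearest low value was that of Mnat1 (Entrez gene 17420), which encodes an assembly factor of the CDK-activating kinase. Its log2 ratio was -0.69 ± 0.12 (SE, n = 4 mice; limma adjusted p = 0.0664), a fold of 0.620, and all 8 arrays lay below 0. The next named genes with 1 sign on all 8 arrays were Letm1 (gene 56384), an inner mitochondrial membrane protein, at -0.46 ± 0.10 (adjusted p = 0.1004), and Calml3 (gene 70405), a calmodulin-like protein, at -0.36 ± 0.084 (adjusted p = 0.109). Zkscan2 (gene 210162), a zinc finger protein, lay at -0.50 ± 0.14 and the secretoglobin gene Scgb1b2 (gene 57426) at -0.57 ± 0.18, which became -0.33 and -0.29 without mouse 4. On the high side, 5 genes lay above 0 on all 8 arrays, at smaller ratios. Their limma adjusted p ran from 0.321 for Zfand5 to 0.549 for Tsc22d1. Of 609 named clones, only these and the 5 lower ones had 1 sign on all 8 arrays. Terf2 (gene 21750), which encodes a telomere-binding protein, lay at 0.24 ± 0.094, Asrgl1 (gene 66514), an asparaginase-like enzyme, at 0.22 ± 0.085, and Zfand5 (gene 22682) at 0.22 ± 0.078. Asph (gene 65973), an aspartate hydroxylase, lay at 0.18 ± 0.075 and Tsc22d1 (gene 21807) at 0.14 ± 0.081. Without mouse 2, Terf2 lay at 0.15 and Tsc22d1 at 0.088. With the mouse in Cy3 and in Cy5, Tsc22d1 lay at 0.22 and 0.059, Terf2 at 0.14 and 0.33, and Zfand5 at 0.13 and 0.31. Calml3 lay at -0.49 and -0.23, and Scgb1b2 at -0.39 and -0.74. The 2 orientations lay closer together for Mnat1, Letm1, Zkscan2, Asrgl1 and Asph. With any 1 mouse left out, 4 of the 10 genes moved by over 1.5 times (Zkscan2, Scgb1b2, Terf2 and Tsc22d1); none could turn in sign, since they were chosen for 1 sign on all 8 arrays. A dimmer second clone of Letm1 lay at 0.078 ± 0.076, and a brighter second clone of Asph at 0.23 ± 0.14, above 0 on 5 of the 8 arrays. The clones for Asrgl1, Terf2 and Scgb1b2 were dim, and none of these 10 genes passed the threshold in the main test.

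**Figure D1:**
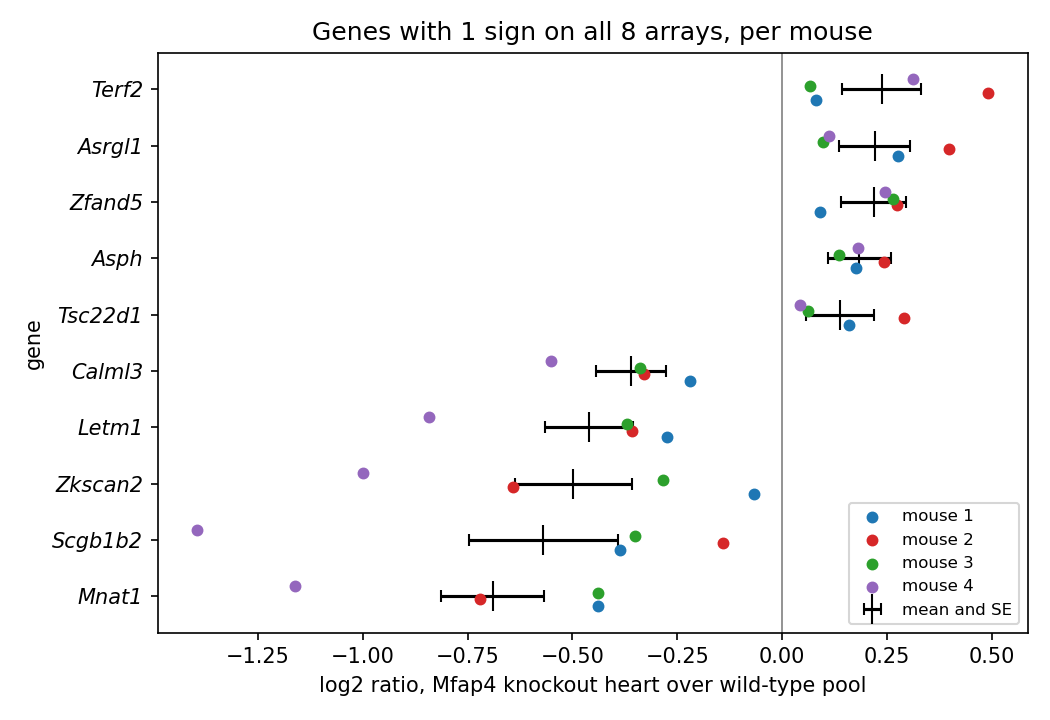
Log2 ratio of knockout heart over wild-type pool (horizontal axis) for the 10 named genes with 1 sign on all 8 arrays (vertical axis). Coloured points are the 4 mice, each the mean of 2 dye-swapped arrays, and black bars are the mean with its SE; Mnat1 lay lowest on average at -0.69 and Terf2 highest at 0.24.

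In limma's test, 0 of 8142 clones passed an adjusted p of 0.05. The count at an unadjusted p under 0.05 was 936, 469 higher and 467 lower, against 407.1 for chance, and the smallest adjusted p was 0.0664. At an adjusted p under 0.1 there were 136 clones, 15 higher and 121 lower. This balance depended on the normalization. With median centring in place of loess, 759 clones passed 0.1, 558 higher and 201 lower. With plain background subtraction 0 of 7677 clones passed in limma (941 at an unadjusted p under 0.05). The count at 0.1 was also 0 with an offset of 10, with all spots kept (20160 clones tested), and with a trended, robust variance prior. It was 0 with the term for mice 1 and 2 against 3 and 4, without the co-varying clones described below, and without mouse 2, 3 or 4. With no background correction, print-tip loess and scale normalization between arrays it was 128, 100 and 123. The count of 0 at 0.05 also depended on the setting: testing only the 3545 brighter clones gave 126 calls at 0.05, 11 higher and 115 lower. The 4 arrays with the mouse in Cy5 alone gave 848 of 11326 tested clones. The 4 with the mouse in Cy3 alone gave 0 of 9839 in limma (1538 at an unadjusted p under 0.05). With 1 orientation the dye effect of a clone stays in its ratio. Leaving out mouse 1 gave 87 calls, while leaving out mouse 2, 3 or 4 gave 0. The clones tested were 8142 without mouse 1 or 2, 11878 without mouse 3 and 9501 without mouse 4.

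Among the brighter clones alone, 5 calls had a gene name. Mnat1, Letm1 and Calml3 fell, with limma adjusted p of 0.0308, 0.0453 and 0.0426 in that setting. With bright clones and all spots kept, Letm1 and Calml3 no longer passed (adjusted p = 0.0550 and 0.05001), nor did Letm1 without the co-varying clones described below (0.0505). Gfra1, a receptor subunit for glial cell line-derived neurotrophic factor, fell by 0.36 on the log2 scale (adjusted p = 0.0387; lower in 4 of 4 mice). Timm10, a chaperone of protein import into mitochondria, rose by 0.37 (adjusted p = 0.0316; higher in 4 of 4 mice). Timm10 lay above 0 on 6 of the 8 arrays and Gfra1 below 0 on 6. Most of both changes came from 1 dye orientation: Timm10 lay at 0.68 with the mouse in Cy5 and 0.052 in Cy3, and Gfra1 at -0.70 and -0.026. None of these 5 passed in the main test of all 8142 clones. Over the same clones with the 8 arrays and mouse as a random block, Mnat1, Letm1 and Calml3 passed (limma adjusted p = 0.0082, 0.0175 and 0.0421). With a dye term added, Mnat1, Letm1 and Gfra1 passed (0.0132, 0.0301 and 0.0413). With median centring Mnat1 passed (0.0374). The fits of 8 arrays do not reduce them to 4 mice, as described below.

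To see whether the lowest clones varied together, a profile was taken from the 30 bright clones with the lowest moderated statistic, and 40 bright clones followed it over the 8 arrays with r over 0.9, 4 of them among the 30. The profile, r and the mean log2 ratios of the 40 were taken with all spots kept, flagged ones included. In this they differ from the log2 ratios of the main test. This number does not set the low clones apart: the same construction from the highest clones gave 57, and under 14 turned sign patterns of the mice it gave 3 to 76, with at least 40 in 8 of them. Only 1 of the 40 had a gene name, Nr1h4, with a log2 ratio of -0.034 over the 4 mice. The median log2 ratio of the 40 was -0.078 in mouse 1, -0.71 in mouse 2, -0.41 in mouse 3 and -1.02 in mouse 4. Among the low genes named above, r was 0.855 for Zkscan2, 0.735 for Calml3, 0.726 for Mnat1 and 0.702 for Letm1. It was 0.129 for Scgb1b2 and -0.544 for Gfra1. Here r measures the pattern over the arrays, not the level. The genes and the profile come from the same arrays, so these values are no separate evidence. For the 5 higher genes r lay between -0.376 and 0.078. Of the 126 calls, 60 had r over 0.8, and the test of bright clones without such clones gave 57. The profile was itself built from the lowest bright clones, so the calls and the profile are not independent.

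**Figure D2:**
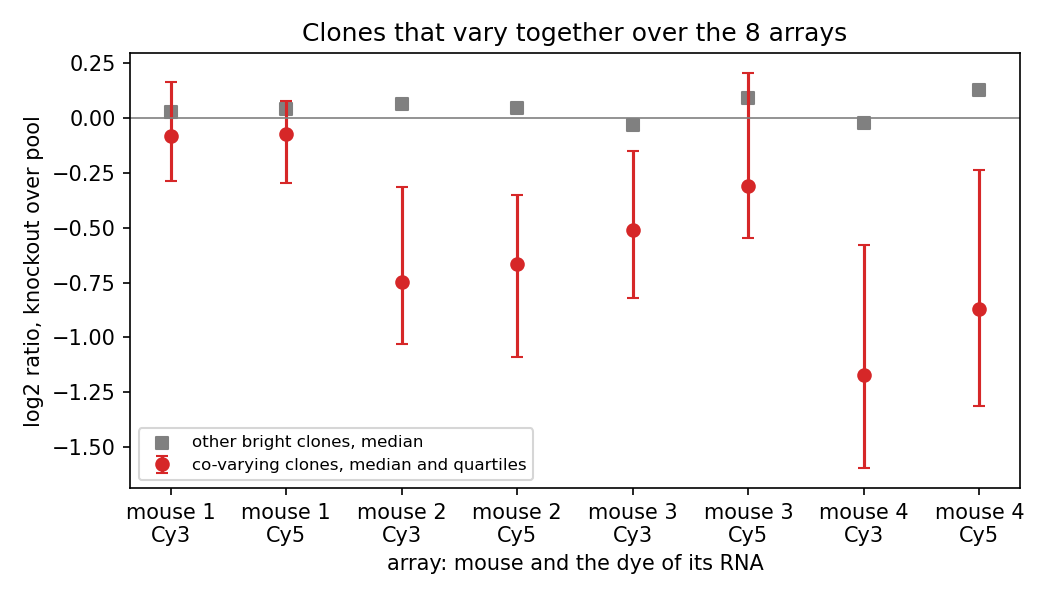
Median log2 ratio of knockout over pool (vertical axis) on each of the 8 arrays (horizontal axis, by mouse and dye) for the 40 clones that follow the profile, with quartiles as bars, and for other bright clones as grey squares. The clones' median lay between -1.17 and -0.074 and below 0 on all 8 arrays.

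The fixed lists asked whether matrix, vascular, heart muscle or other cell type genes differed. Single values below often rest on 1 mouse, so ranges with 1 mouse left out are given. The arrays named 89 of the 768 list genes, and 55 were tested. All 55 log2 ratios lay between -0.29 and 0.27, and 0 passed the limma threshold, with 4 at an unadjusted p under 0.05. Among integrin and focal adhesion genes, 3 were tested and all lay above 0. Ilk, the integrin-linked kinase, lay at 0.27 ± 0.089 (SE, n = 4 mice; limma adjusted p = 0.271), and 1 gene of this list, Ilk, passed when adjusted over the list alone. Its log2 ratio was 0.67 on the arrays with the mouse in Cy5 and -0.13 with the mouse in Cy3. Zyx, a focal adhesion protein, lay at 0.16 ± 0.10 (0.052 to 0.24 with 1 mouse left out). The clones for Ilk and Zyx were dim. Of the list of fibrillar collagens and collagen processing, 2 genes were tested, and the collagen gene Col5a3 lay at 0.018 ± 0.079. Pcolce, which enhances procollagen cleavage, lay at -0.29 ± 0.11 and below 0 in 4 of 4 mice (-0.37 to -0.16 with 1 mouse left out). Nearly all of it came from 1 dye orientation, -0.55 with the mouse in Cy3 against -0.029 in Cy5; for Zyx these values were 0.28 and 0.044. Of 2 elastic fibre genes, Mfap5, another microfibril protein, lay at 0.067 ± 0.086, and at 0.0011 without mouse 3 (0.12 without mouse 4); with the mouse in Cy5 it lay at 0.18 and in Cy3 at -0.050.

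Fibroblast, ribosomal and macrophage genes were the lists with 5 tested genes, and limma's camera called 0 of these 3 (adjusted p = 0.911 for each). With an estimated correlation the p-values were 0.916, 0.767 and 0.925, and fry also called 0. Of the fibroblast genes, 4 lay above 0 and 1 below, with Ddr2, a collagen receptor, lowest at -0.14 ± 0.092 (-0.052 without mouse 3; -0.37 with the mouse in Cy3 and 0.097 in Cy5). Of the macrophage genes, 2 lay above 0 and 3 below, with a median of -0.080: Lyz2 lay at 0.18 ± 0.10 and Csf1r at 0.17 ± 0.091, while the complement gene C1qa lay at -0.11 ± 0.082. With 1 mouse left out these ran from 0.11 to 0.28, from 0.096 to 0.24 and from -0.15 to -0.067. C1qa lay at -0.27 with the mouse in Cy5 and 0.049 in Cy3, and Lyz2 at 0.073 and 0.29. The clones for Ddr2, Csf1r and C1qa were dim. Of the ribosomal genes, Rpl6 was highest at 0.14 ± 0.10, and lay at 0.047 without mouse 4 and 0.23 without mouse 1. All 5 tested ribosomal genes had bright clones. The ribosomal list passed with median centring in place of loess (adjusted p = 0.0176, median 0.30) and with the authors' value table (adjusted p = 0.0239, median 0.16), but not in either once the correlation between genes was estimated (0.919 and 0.869, adjusted p = 0.854 and 0.869).

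Heart muscle, vessel and metabolic genes were few. Of 3 sarcomere genes, 2 lay above 0 and 1 below; Mybpc3 lay at 0.11 ± 0.078 (0.068 to 0.13 with 1 mouse left out; 0.24 with the mouse in Cy5 and -0.025 in Cy3) and Myom2 at 0.12 ± 0.089 (0.032 to 0.16). Notch3, a receptor of vascular smooth muscle, lay at 0.18 ± 0.091 (0.12 to 0.26), and the chemokine gene Cxcl12 at 0.18 ± 0.097 (0.099 to 0.27). Cxcl12 lay at 0.34 with the mouse in Cy5 and 0.0091 in Cy3. The 4 glycolysis genes had a median of 0.0089, with Ldha, a subunit of lactate dehydrogenase, highest at 0.21 ± 0.10 (0.14 to 0.30). Of 2 cell cycle genes, 1 lay above 0, Ccnd2, a D-type cyclin, at 0.22 ± 0.092 (0.14 to 0.29), and 1 below. Cd4 was the only tested lymphocyte gene, at 0.24 ± 0.082, and passed when adjusted over the list alone, which held that 1 gene. It lay at 0.51 with the mouse in Cy5 and -0.041 in Cy3. Sptb, a red blood cell gene, lay at 0.11 ± 0.084 (0.072 to 0.17), with 0.41 in Cy5 and -0.19 in Cy3. None of these passed over all clones in the main test. With median centring in place of loess, Ldha lay at 0.47 and passed (limma adjusted p = 0.0349). Mybpc3 at 0.40, Myom2 at 0.39 and Ccnd2 at 0.30 also lay higher there and did not pass. Notch3, Cxcl12, Cd4 and Sptb lay lower there than in the main test. The direction went with brightness: the clones for Ldha, Mybpc3, Myom2 and Ccnd2 were bright, and those for Notch3, Cxcl12, Cd4 and Sptb dim. Median centring leaves in any part of a ratio that varies with intensity, so these shifts are no evidence of a knockout effect.

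Genes near Mfap4 on chromosome 11 were examined as a check of the targeted locus. Of 11 named genes within 5 Mb, 6 were tested, 4 above 0 and 2 below, with a median log2 ratio of 0.017, whose sign changed between settings. The exact two-sided sign test gave p = 0.688, and limma's camera p = 0.428 for this set. Zfp692 lay at -0.25 ± 0.098 (SE, n = 4 mice; limma adjusted p = 0.378) and Arhgap44 at -0.16 ± 0.098, and which was lower depended on mouse 3: without it they lay at -0.15 and -0.25. Without mouse 2 Arhgap44 lay at -0.073. The clones for Zfp692 and Arhgap44 were dim. At an unadjusted p under 0.05 there was 1 of the 6, Zfp692, against 53 of the 580 other named genes (Fisher's exact test, p = 0.442, chosen after the data were seen).

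Clone-specific dye effects passed the threshold more often than knockout effects. Across clones, log2 ratios of arrays of like dye orientation correlated at r from 0.119 to 0.496. The 2 dye-swapped arrays of a mouse correlated at r from -0.309 to -0.024, and clones are not independent replicates. In a limma fit of all 8 arrays with a dye term and mouse as a random block, 1220 clones had a dye effect at an adjusted p under 0.05 and 169 a knockout effect, 17 higher and 152 lower.

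**Figure D3:**
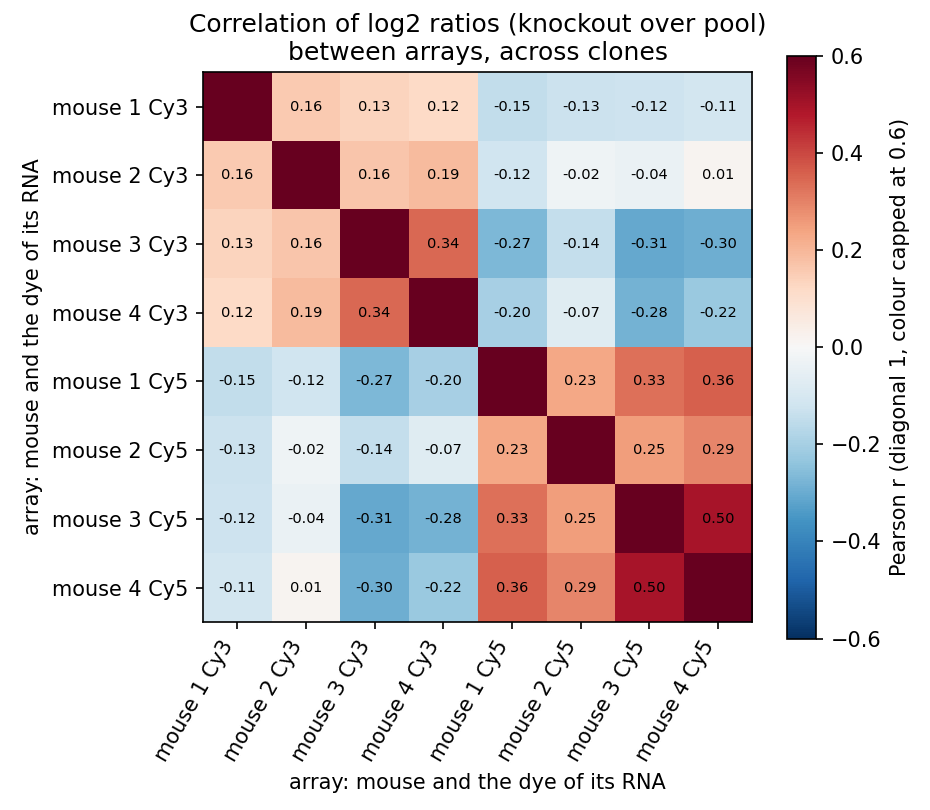
Pearson correlation across clones of the log2 ratio of knockout over pool between the 8 arrays, ordered by dye and then mouse on both axes; the colour scale stops at 0.6 in size. Arrays of like dye orientation correlated at 0.119 to 0.496 and those of opposite orientation at -0.309 to 0.014.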

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

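The sign-pattern test and the test over mouse medians were chosen after the results were seen; the print-neighbour and dye tests were set down before their values were known. Among 19 groups of 4 mice or 8 arrays, 4 held a value far from the others, where chance gives about 0.95.

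For Zfand5, mouse 1 lay at 0.090 and the next mouse at 0.24, a gap of 0.835 of the range over the 4 mice. For Letm1, mouse 4 lay at -0.84 and the next mouse at -0.37, a gap of 0.833 of the range. The array of mouse 2 with its RNA in Cy3 had an SD of log2 ratios of 0.320, against 0.380 on the next array, a gap of 0.657 of the range. On the same array 35.9% of spots exceeded 2 times the background in Cy3, against 18.8% on the next, a gap of 0.549 of the range.

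The 40 clones that follow the profile had a median log2 ratio of -0.55 ± 0.40 (SD, n = 4 mice). Position on the slide is argued against by the 25 bright clones printed next to them, which had a median of -0.0078 ± 0.014 (SD, n = 4 mice), although the 40 were spread unevenly over the print blocks (permutation p = 0.0162). Dye bias and noise of single arrays were examined on another set, 182 clones chosen on the Cy3 arrays alone. Their median on the Cy5 arrays was -0.28 ± 0.21 (SD, n = 4 arrays), below 0 on each. In mice 1 to 4 it was -0.078, -0.44, -0.13 and -0.47, so it was small in mice 1 and 3. These values argue against dye bias and noise of single arrays for the 182. Their overlap with the 40 is not given here. Whether loss of Mfap4 is the cause of the low values of the 40 stays open. The exact two-sided sign-flip test (p = 0.125, the smallest that 4 mice allow) decides nothing. The 40 were chosen by following a profile that was built from the lowest clones in the same mice. The pool's own make-up is also confounded with the knockout. One transcript shared by these mostly unnamed clones was not tested, since clone sequences were not used here.

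The count of 936 clones at an unadjusted p under 0.05 was compared with the other sign patterns of the 4 mice. Of the 8 distinct patterns, 1 gave as many, the real one, and the highest of the others gave 521. With 8 patterns no share under 0.05 can be reached. The pattern that sets mice 1 and 2, without spot flags, against mice 3 and 4 gave 198.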

How the results depend on the processing

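The centred value table, the term for mice 1 and 2 against mice 3 and 4, and the settings that combine bright clones with all spots or leave out co-varying clones, and an estimated correlation in those list settings, were chosen after seeing the data. The count of 0 clones at an adjusted p of 0.05 became 136 with median centring (73 higher, 63 lower), 126 with bright clones only, 91 with bright clones and all spots kept, and 57 with bright clones without the co-varying ones. It became 174 with 8 arrays and mouse as a random block, and 169 with a dye term added. The fitted correlation between the arrays of a mouse was -0.33 and -0.044, so neither fit reduced the 8 arrays to 4 replicates. Treating the 8 arrays as separate replicates gave 89. The mouse in Cy5 only gave 848 of 11326 tested clones, against 0 of 9839 in Cy3 only (1538 at an unadjusted p under 0.05 in limma). Leaving out 1 mouse gave 0 to 87, the 87 without mouse 1, and a threshold of 0.1 gave 136. With bright clones only, the 5 named calls had smaller SEs (Timm10 0.067, main test 0.078). The causes were not tested. The other settings gave 0, with 16082 clones tested for the deposited values.

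The count of 0 lists became 1, the ribosomal list, with median centring, with the deposited values and with those values centred, and 0 in each with an estimated correlation; leaving out any 1 mouse gave 0. The median near Mfap4 turned to -0.0055 with no background correction, -0.066 with the mouse in Cy3 only, -0.050 in Cy5 only, -0.21 with the deposited values and -0.030 with these centred; leaving out 1 mouse gave -0.068 to 0.051. The cause was not tested. Mfap4 was not measured under a name, so its alternatives were not run.

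Over 229 pairs of the 10 named genes and an alternative, 215 kept direction and side of the threshold. In 14 the gene passed it in the same direction (Mnat1, Letm1 and Calml3), and 0 turned. The size of the log2 ratio moved widely: Terf2 ran from 0.077 to 0.59, Asrgl1 from 0.12 to 0.82 and Scgb1b2 from -1.31 to -0.29. Letm1 ran from -0.52 to -0.19 and Mnat1 from -0.84 to -0.51. These 10 were chosen for 1 sign on all 8 arrays, so settings that leave out arrays could not turn them, and the 0 is no measure of stability. For the 23 other genes, 494 of 516 pairs kept both, 11 passed the threshold in the same direction (Ilk, Ldha, Timm10 and Gfra1) and 11 turned. With 1 mouse left out, 18 of the 23 moved by over 1.5 times and 0 turned. With the mouse in Cy3 only, the log2 ratio turned for Ilk (-0.13), Cd4 (-0.041), Mybpc3 (-0.025), Mfap5 (-0.050), C1qa (0.049), Hsp90b1 (-0.049), C1s1 (-0.028) and Sptb (-0.19). Ddr2 turned in Cy5 only (0.097), for causes not tested. The deposited values turned Mfap5 (-0.0055) and Sptb (-0.022); their median over clones was -0.16, and once centred they gave 0.17 and 0.16, so the offset accounts for both turns. Signal over background limits the values, since 3585 of 20160 clones were bright.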

Other observations

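The co-varying clones and the tests of their make-up were chosen after the data were seen. The number of such clones depends on how the profile is set up. With the 30 bright clones of lowest mean log2 ratio in place of those with the lowest moderated statistic, 68 clones followed the profile with r over 0.9, 24 of them among the 40. Their medians were -0.19, -0.78, -0.51 and -1.21 in mice 1 to 4.

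Of the 40 clones, 7 came from the MG-26 plates of the clone library, which hold 115 of the 3585 bright clones (Fisher's exact test, p = 0.000226). No accession was given for 35% of the 40, against 19.7% of other bright clones (Fisher's exact test, p = 0.0258). These are 2 of several properties looked at, without adjustment.

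Among stress and complement genes outside the comparisons above, both named after their values were seen, Hsp90b1, a chaperone of the endoplasmic reticulum, had a log2 ratio of 0.12 ± 0.074 (SE, n = 4 mice), with the 4 mice between 0.096 and 0.13. The complement gene C1s1 lay at 0.18 ± 0.096 (0.13 to 0.28 with 1 mouse left out). Both came from 1 dye orientation: with the mouse in Cy5 they lay at 0.28 and 0.38, in Cy3 at -0.049 and -0.028.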
